A study of Homo sapiens with 179 samples.

How the data were processed

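RNA was sequenced from the human embryonic stem cell line H1, grown on Matrigel in the defined medium E8. Per the labels, 6 libraries came from a commercial TruSeq RNA kit and 173 from LM-Seq, a strand-specific protocol that selects polyadenylated RNA with oligo-dT and primes reverse transcription with random hexamers. The titles place the TruSeq libraries in the groups H1p16 and H1p43, with 3 replicates each. They place the LM-Seq libraries in Lane 1 (n = 95), Lane 2 (n = 48), Lane 3 (n = 24) and Lane 4 (n = 6), so that the number of samples sharing a lane sets the depth. What the letter p stands for, and what sets the LM-Seq libraries of a lane apart, is not given in the sources used here. Each LM-Seq library carries a 5-digit number that recurs across lanes and served as its replicate number. The labels do not say whether a number marks 1 library sequenced in several lanes; if it does, differences between lanes reflect sequencing alone and not separate preparations. Nothing in the labels says whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

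Per the submitters' processing notes, CASAVA 1.8.2, Bowtie 0.12.8 and RSEM 1.2.3 were used with the genome build hg19. The authors deposited expected counts per gene, as RSEM estimates them, and TPM values, which scale such counts by transcript length and by the library total. Both tables hold 19084 genes, named by symbol with RefSeq transcript identifiers, for all 179 libraries. They give no coordinates, and none are printed. RSEM divides reads that align to several genes by its model, so values of near-identical paralogs and read-through gene models are uncertain, and so are those of overlapping and antisense genes, because the sources used here do not say whether strand entered the counting.

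Expected counts were rounded to whole numbers and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after filterByExpr and TMM normalization, with no covariates. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. Standard errors of log2 fold changes were derived from the fold change and its quasi-likelihood F statistic. The comparisons were H1p43 with H1p16, LM-Seq Lane 4 with all TruSeq libraries, and Lanes 2, 3 and 4 with Lane 1 over the library numbers that both lanes hold. The design, the alternatives, 33 gene lists and the rule for named genes were fixed before the data were examined. The rule took the 8 largest changes in each direction (4 for lanes) among called genes with a mean of at least 5 TPM in the higher group and, in groups of 3 or 6, no overlap between groups. It added up to 3 called members per list with the lowest adjusted p, further list members as examples, and POU5F1, NANOG and SOX2.

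Lists with at least 3 tested members were compared with all other genes by camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over lists. The camera test was repeated with the correlation estimated from the data. The fry test, which asks whether the genes of a list moved on balance in one direction and makes no comparison with other genes, was also run. Numbers of genes detected were compared by sign-flip permutation of paired differences, and correlations by permutation of library numbers, exactly for 6 numbers and with 100000 resamples otherwise. Correlations over genes used log2(TPM + 1), and genes are not independent replicates.

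Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, limma on log2(TPM + 1) for genes with a mean of at least 1 TPM, a minimum fold change, thinning of counts to a common total, omission of each TruSeq replicate, other lanes, and the replicate number as a block. Same-numbered LM-Seq libraries deviated together from their lane means: the correlation of deviations from Lane 1 ranged from 0.168 to 0.639 in Lane 2, from 0.226 to 0.551 in Lane 3 and from 0.359 to 0.437 in Lane 4. All of these pairs exceeded 0.1, so blocked counts are given beside the unblocked ones. Libraries within a group were checked for duplicates. The chi-square per degree of freedom between them, about 1 for counting noise alone, was at least 1.29 in TruSeq and at least 1.34, 1.60, 2.24 and 5.79 in Lanes 1 to 4. Its excess over 1 grows with counts per gene, so these values do not rank groups of unlike depth. At a common total, the biological coefficient of variation over the 6 numbers in all 4 lanes was 0.061, 0.059, 0.058 and 0.060 in Lanes 1 to 4.

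The calling procedure was tested on simulated counts with 100 genes changed at each of 2 fold sizes. For H1p43 against H1p16, over 14574 genes, 90 of the genes changed 2-fold were recovered and 20 of 14374 unchanged genes were called. For Lane 4 against TruSeq, over 13827 genes, 77 were recovered and 7 of 13627 unchanged genes were called. For Lane 4 against Lane 1, over 12419 genes, 80 were recovered at 2-fold and 55 at 1.5-fold. The simulation drew libraries independently and left nearly all genes unchanged. It does not show how calling performs where most genes differ or where same-numbered libraries deviate together. GC content and length came from GENCODE transcripts, found through RefSeq identifiers for 18537 genes and by symbol for 333, which left 214 without a match. A gene at 0 counts in a whole group was given a bound from a floor of 3 counts over the group, which covers counting error only. Y-linked genes and a gene of X inactivation were left out of the named genes, and 2 genes that the rule selected are not reported here.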

Results

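The data comprised 179 RNA-seq libraries of H1, an established human embryonic stem cell line. TruSeq libraries held 23680509 to 30628671 expected counts in H1p16 and 29018110 to 35852620 in H1p43, with 12 samples per lane. LM-Seq libraries held 1040667 to 1539268 in Lane 1, 2005728 to 2739067 in Lane 2, 4028604 to 4918554 in Lane 3 and 15780048 to 16583038 in Lane 4. Lane 4 was therefore the LM-Seq lane nearest in depth to TruSeq.

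The first comparison asked how the H1p16 and H1p43 libraries differed within one protocol. NPTX1, which encodes a neuronal pentraxin, rose from 1.94 ± 0.19 TPM in H1p16 to 25.4 ± 1.1 TPM in H1p43 (SD, n = 3 each), a log2 fold change of 3.61 ± 0.06 (SE). Metallothioneins, small proteins that bind zinc and copper, fell: MT1G went from 199 ± 10.4 to 3.39 ± 0.55 TPM, a log2 fold change of -5.97 ± 0.10. Regulators of the pluripotent state fell less, with DNMT3B, a de novo DNA methyltransferase, at -1.03 ± 0.02, L1TD1, an RNA-binding protein of pluripotent cells, at -1.08 ± 0.02 and PRDM14, a transcriptional regulator, at -1.40 ± 0.03. The core factors POU5F1, NANOG and SOX2 fell by 0.16, 0.24 and 0.29 on the log2 scale. HSPA8, a constitutive chaperone, dropped from 3443 ± 51.9 to 1668 ± 3.11 TPM.

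Among the 8 largest increases were also GRM3, a metabotropic glutamate receptor (2.64 ± 0.12), JAKMIP1 (2.51 ± 0.15), SLC1A1, a glutamate transporter (2.16 ± 0.06), SBK2 (2.15 ± 0.20), GNAZ, a G protein subunit (2.14 ± 0.10), STON1 (2.14 ± 0.07) and KCNG1, a potassium channel subunit (2.11 ± 0.07). The largest decreases included MT1H (-6.26 ± 0.16), MT1E (-5.28 ± 0.21), MT1F (-4.10 ± 0.12) and MT2A (-2.62 ± 0.10), whose close sequence similarity leaves the division of reads among them uncertain. RTP1 (-3.45 ± 0.18) and HES3, a repressor of the HES family (-2.32 ± 0.08), completed that set with the read-through model PPAN-P2RY11 (-3.21 ± 0.46), which DESeq2 did not call (adjusted p = 0.107). The adjusted p in edgeR was 6.4e-18 for NPTX1 and MT1G and 6.2e-06 for PPAN-P2RY11, the highest among these 16 genes.

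**Figure D1:**
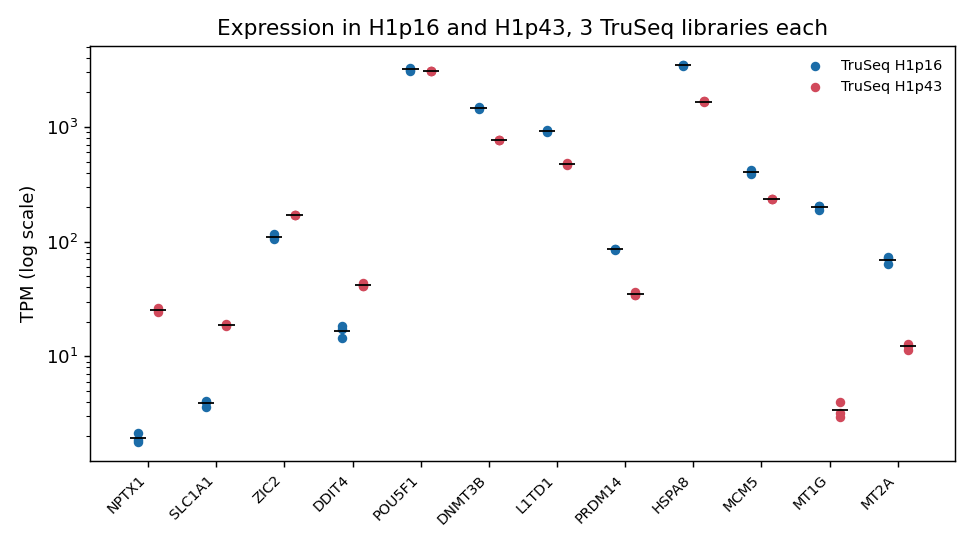
TPM on a log scale of 12 genes in the 3 H1p16 and 3 H1p43 TruSeq libraries; points are libraries and bars are group means. NPTX1 lay at 1.94 TPM in H1p16 and 25.4 TPM in H1p43 on average, and MT1G at 199 and 3.39 TPM, while POU5F1 stayed near 3191 and 3070 TPM.

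In edgeR's quasi-likelihood test, 10460 of 14574 genes changed (71.8%), of which 5305 were higher and 5155 lower in H1p43. A fold change of at least 2 left 1061 genes, 829 higher and 232 lower. Expression did not overlap between groups for 73.7% of genes, where chance gives 10% for 3 libraries against 3. The share of higher calls was 50.7%, but 64.2% with limma on log2(TPM + 1), where the median of all genes lay at 0.09. The common biological coefficient of variation between replicates was 0.022, so small changes passed the test. Pairs of H1p43 libraries differed by a chi-square per degree of freedom of 1.29 to 1.38, near counting noise, and pairs of H1p16 by 1.91 to 4.08. This spread may be technical, so the p-values need not hold for separate cultures.

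Of 29 lists tested, 6 were called by camera, all toward lower expression in H1p43, and none with an estimated correlation. In the pluripotency list 19 of 22 genes fell and 1 rose (median log2 fold change -0.52; adjusted over the list alone, 20 fell), with an adjusted p = 5.9e-06 by camera and an adjusted p = 0.106 with an estimated correlation. Of 17 G1/S genes, 13 fell (14 adjusted over the list alone; median -0.40), among them RRM2, a ribonucleotide reductase subunit (-1.05 ± 0.02), and the replicative helicase subunits MCM5 (-0.89 ± 0.03) and MCM7 (-0.50 ± 0.02). Its adjusted p was 4.2e-05 by camera, with an adjusted p = 0.106 with an estimated correlation. In the cholesterol synthesis list, 14 of 19 genes fell and 1 rose (14 lower adjusted over the list alone; median -0.36), including SQLE (-0.63 ± 0.02). Its adjusted p was 0.0035 by camera, with an adjusted p = 0.174 with an estimated correlation.

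Of 11 heat shock genes, 9 fell and 1 rose (9 lower adjusted over the list alone; median -0.24), with HSPA8 at -1.16 ± 0.02 and the inducible HSPA1B, which shares reads with a near-identical copy, at -0.64 ± 0.04. The adjusted p was 0.0083 by camera, and there was an adjusted p = 0.205 with an estimated correlation. Of 17 glycolysis genes, 13 fell and 3 rose (13 lower adjusted over the list alone; median -0.24), LDHA by 0.64 and GAPDH by 0.31 among the decreases; LDHA had a log2 fold change of -0.64 ± 0.02 and GAPDH of -0.31 ± 0.01. Camera gave an adjusted p = 0.0139 and an adjusted p = 0.246 with an estimated correlation. Of 83 cytosolic ribosomal protein genes, 46 fell and 7 rose (46 lower adjusted over the list alone; adjusted p = 0.0255 by camera, and adjusted p = 0.846 with an estimated correlation). Their median was only -0.06, against 0.01 over all genes, and 0.05 on the TPM scale, against 0.09 over all genes.

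Markers of other cell types went in both directions. In the neuroectoderm list 7 of 9 genes rose and 1 fell (median 0.52; 7 higher adjusted over the list alone), with POU3F1 at 1.06 ± 0.05, MAP2 at 1.45 ± 0.07 and ZIC2 at 0.52 ± 0.03; the list did not pass camera (adjusted p = 0.114). In the fibroblast or stroma list 8 of 12 rose and 2 fell (median 0.39; 8 higher adjusted over the list alone), with COL1A2, a collagen chain, at 0.68 ± 0.03, PDGFRB at 0.80 ± 0.05 and TAGLN at 0.42 ± 0.03, and camera gave an adjusted p = 0.0576. In the primitive streak and mesoderm list 4 of 7 fell and 2 rose (4 lower and 2 higher adjusted over the list alone; median -0.98, but -0.61 on the TPM scale), KDR, a growth factor receptor, among them at -0.98 ± 0.03, with an adjusted p = 0.258 by camera.

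The next comparison set LM-Seq beside TruSeq, with the 6 libraries of Lane 4 against all 6 TruSeq libraries. The TruSeq side pooled H1p16 and H1p43, which differed from each other. A change against their mean need not hold against each of them. HSPA8, for example, averaged 2887 TPM in Lane 4, between 3443 TPM in H1p16 and 1668 TPM in H1p43. Cytosolic ribosomal protein genes were lower in LM-Seq, and their sum was 11.4% ± 0.22 of all TPM in Lane 4 and 22.1% ± 0.44 in TruSeq (SD, n = 6 each). RPS29 fell from 2631 ± 153.5 to 91.9 ± 21.1 TPM, a log2 fold change of -4.66 ± 0.10 (SE), and RPS27 from 5014 ± 181 to 231 ± 31.4 TPM (-4.41 ± 0.08). CCND2, a G1 cyclin, rose from 29.7 ± 1.27 to 219 ± 8.48 TPM (2.92 ± 0.06), and CD9, a tetraspanin of the stem cell surface, from 180.3 ± 5.68 to 718 ± 41.2 TPM (2.03 ± 0.05). POU5F1 (-0.54 ± 0.05) and SOX2 (-0.69 ± 0.08) were lower and NANOG (0.29 ± 0.07) higher in LM-Seq. For NANOG the groups overlapped, and with Lane 3 in place of Lane 4 the log2 fold change was 0.13 and no longer called.

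**Figure D2:**
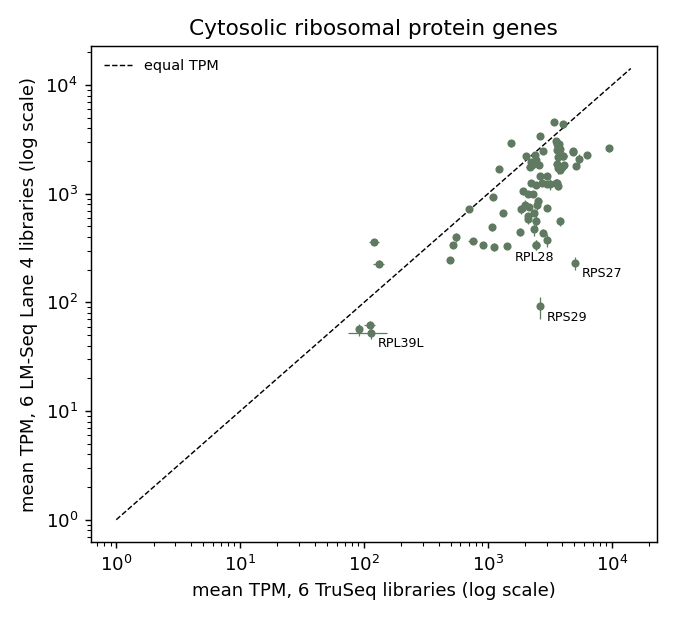
Mean TPM of 82 cytosolic ribosomal protein genes in the 6 TruSeq and the 6 LM-Seq Lane 4 libraries, both axes on log scales, with bars of 1 SD and a dashed line of equal TPM. Of these genes, 73 lay below the line, RPS29 at 91.9 and RPS27 at 231 TPM in LM-Seq.

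Some genes were at 0 in all 6 TruSeq libraries or in all 6 libraries of Lane 4. PNMA6A was at least 254-fold and MRAP, an accessory protein of the melanocortin receptors, at least 167.96-fold higher in Lane 4, and MAGED4 at least 1109-fold and the read-through model GPR75-ASB3 at least 372-fold lower. MAGED4 has the near-identical copy MAGED4B and PNMA6A similar copies, so their values and these bounds are uncertain. Increases also included NARR (7.34 ± 0.58), which shares its locus with another gene, C1orf229 (4.95 ± 0.30), PMCH, which encodes a melanin-concentrating hormone precursor (4.10 ± 0.51), and ZNF483 (3.88 ± 0.10), together with POU5F1B (4.29 ± 0.35) and RGPD6 (3.94 ± 0.54), near-identical copies of other genes. Decreases included the histone gene HIST1H4J (-4.81 ± 0.69), which was above 0 in only 1 library of Lane 4 and at least 147.6-fold lower without it. They also included CHCHD10 (-4.62 ± 0.37), CCL26, a chemokine (-4.55 ± 0.51), and FAM21B, a member of a family of near-identical genes (-4.45 ± 0.64).

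In the ribosomal protein list 71 of 82 genes fell and 8 rose (71 lower adjusted over the list alone; median -0.99), the only list of 29 that camera called (adjusted p = 4.2e-16, and adjusted p = 0.89 with an estimated correlation). Members of other lists moved apart. In the pluripotency list 12 of 22 rose and 5 fell (12 and 5 adjusted over the list alone), TDGF1, a co-receptor of NODAL, at 1.03 ± 0.04 and SFRP2, a secreted WNT modulator, at -1.40 ± 0.08. Of 11 heat shock genes 7 rose and 3 fell (7 and 3 adjusted over the list alone), the mitochondrial chaperonins HSPD1 (1.32 ± 0.05) and HSPE1 (0.96 ± 0.06) against HSPB1 (-1.47 ± 0.09). In the cholesterol list 11 of 19 rose and 4 fell (11 and 4 adjusted over the list alone), STARD4 at 2.19 ± 0.06 and CYP51A1 at 1.76 ± 0.10 against SREBF2, its transcriptional regulator, at -1.32 ± 0.05.

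In edgeR's quasi-likelihood test 9852 of 13827 genes differed (71.3%), 4747 higher and 5105 lower in Lane 4, and 3329 differed at least 2-fold, 1247 higher and 2082 lower. Against the H1p16 libraries only, 9230 genes differed, and against the H1p43 libraries only, 10318. Protocol, lane and number of samples per lane all changed between LM-Seq and TruSeq. The labels do not say whether the same culture of H1 was used. With Lane 3, 2 or 1 in place of Lane 4, 9855, 9516 and 8950 genes still differed from TruSeq. The median size of log2 fold changes was 0.07 between Lanes 4 and 1, against 0.59 between Lane 4 and TruSeq. These values argue against the number of samples per lane as the main cause. Protocol, culture and the lane of TruSeq could not be separated. The libraries of Lane 4 varied more than the TruSeq replicates at the same total of 15780048 counts. The biological coefficient of variation was 0.115, against 0.031 in H1p16. In H1p43 the estimate lay at its lower limit of 0.010, so the spread there was too small to be measured this way. What sets the libraries of Lane 4 apart is not given, and TruSeq replicates may be technical. These values therefore do not compare how well the 2 protocols repeat.

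Comparisons of LM-Seq lanes asked what fewer counts per library did to the same library numbers. The number of genes with at least 1 count was 13260 ± 114.3 in Lane 1 (SD, n = 95), 13851 ± 117.7 in Lane 2 (n = 48), 14311 ± 121.4 in Lane 3 (n = 24) and 14831 ± 95.2 in Lane 4 (n = 6). Same-numbered libraries gained 622 ± 46.9 genes from Lane 1 to Lane 2, 1084 ± 53.4 to Lane 3 and 1569 ± 66.6 to Lane 4. The gain was seen in 48 of 48, 24 of 24 and 6 of 6 numbers, with a two-sided permutation p of 1e-05, 1e-05 and, by the exact test, 0.03125, each the smallest its test can give (adjusted p = 1.5e-05, 1.5e-05 and 0.03125 over the 3 lanes by the same permutation tests). After thinning to a common total the gain shrank to 18.9 ± 40.3, 28.3 ± 44.5 and 32.5 ± 50.2 genes. The gains of Lanes 2 and 3 still passed the permutation test (p = 0.002 and 0.005), with 31 of 48 and 17 of 24 numbers higher. That of Lane 4, with 6 numbers, no longer passed the exact permutation test (p = 0.219).

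**Figure D3:**
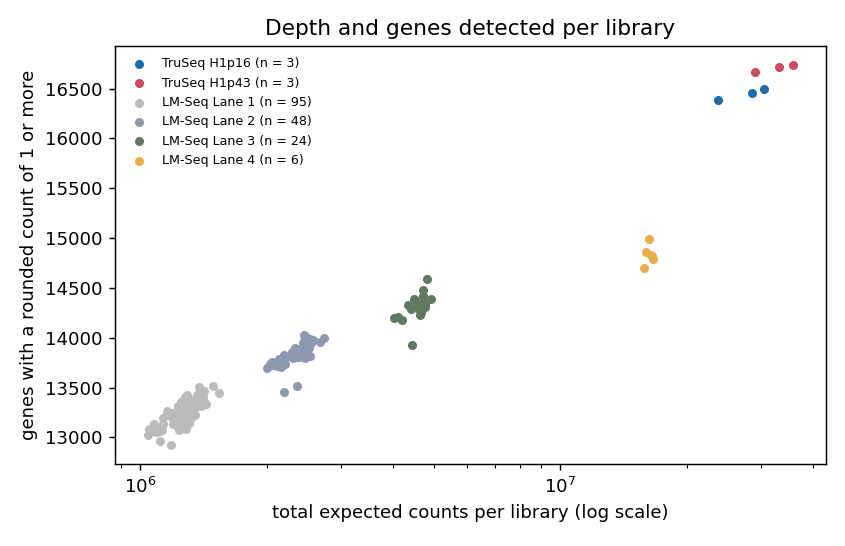
Genes with a rounded count of at least 1 against total expected counts per library on a log scale; each point is one of the 179 libraries, coloured by group. Detection averaged 13260 genes in Lane 1, 14831 in Lane 4 and 16707 in TruSeq H1p43.

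Expression levels moved little with depth. Over genes with at least 20 counts in a pair, same-numbered libraries of Lane 1 and another lane differed by a chi-square per degree of freedom of 1.04 to 1.2. Counting noise alone gives about 1. Different numbers paired with Lane 1 gave 1.43 to 5.33 in Lane 2 and 1.54 to 5.88 in Lane 3. In Lane 4 they gave 1.77 to 2.47, and within Lane 1 they gave 1.34 to 8.33. Same numbers thus differed by little more than counting noise, as 1 library sequenced again would, though the labels do not say so. POU5F1 averaged 2157 ± 73.5 TPM in Lane 1 and 2101 ± 69.8 TPM in Lane 4 over the 6 shared numbers, a log2 fold change of -0.04 ± 0.04, and SOX2 and NANOG differed by 0.04 ± 0.06 and -0.07 ± 0.06. Same-numbered libraries deviated together, which a fit without a block counts as noise, so such fits can miss small differences. Without a block, edgeR called 0 of 10120 genes in Lane 2 and 0 of 10871 in Lane 3, and DESeq2 and limma called 0. At an unadjusted edgeR p below 0.05 there were 182 and 216 genes, fewer than chance gives. With all libraries of both lanes, 60 genes were called in Lane 3. In Lane 4, 2 of 12419 genes were called without a block, by edgeR, DESeq2 and limma, but 0 on counts thinned to a common total. Both were at 0 in all 6 libraries of Lane 1: SERF1A was at least 34.1-fold and the read-through model FAM47E-STBD1, named after its values were seen, at least 7.73-fold higher in Lane 4. With all libraries of both lanes neither was called (log2 fold changes of 1.4 and 0.07), and SERF1A averaged 14.1 ± 25.6 TPM over the 95 libraries of Lane 1, with 71 at 0. SERF1B, a near-identical copy of SERF1A also picked after the fact, averaged 63.4 ± 4.64 TPM in Lane 1 and 16.3 ± 18.1 TPM in Lane 4 over the 6 shared numbers, but 46.7 ± 29.2 TPM over the 95 libraries of Lane 1. With the library number as a block the counts were 26, 44 and 13, or 6, 14 and 4 on thinned counts. Of the former, 23, 37 and 8 had a log2 fold change under 0.1 in size. The larger ones in Lane 4, listed after the fact, again included SERF1A and FAM47E-STBD1. The others were SMN2 (1.26 ± 0.15), the read-through model PHOSPHO2-KLHL23 (0.85 ± 0.13) and CDK11B (0.36 ± 0.07). With all libraries of both lanes SMN2 was at -0.09 and not called. The small calls included NCL, a nucleolar protein, at -0.02 in Lane 3 and 0.02 in Lane 4, and HNRNPA2B1, at -0.02 in Lane 3 and 0.02 in Lane 4. Both were singled out after the fact, and their direction reversed between these lanes. None of 29 lists was called between Lane 4 and Lane 1 by camera, with the preset or an estimated correlation, or by fry.

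Libraries with the same number correlated more closely across lanes than libraries with different numbers. Over genes, the mean Pearson correlation with Lane 1 was 0.984 against 0.978 for Lane 2, 0.987 against 0.980 for Lane 3 and 0.989 against 0.983 for Lane 4. The one-sided permutation p was 1e-05, 1e-05 and, over the 720 orders of the exact test, 0.00139, each the smallest possible (adjusted p = 1.5e-05, 1.5e-05 and 0.00139 over the 3 lanes by the same permutation tests), and all 48, 24 and 6 numbers correlated best with their own. For the 6 numbers in all 4 lanes, the median SD of log2(TPM + 1) between libraries fell from 0.272 in Lane 1 to 0.216, 0.182 and 0.156 in Lanes 2, 3 and 4. On log2 CPM of counts thinned to a common total there was no such fall, with 0.267 in Lane 1 and 0.268, 0.263 and 0.264 in Lanes 2, 3 and 4. Between lanes of one number the SD of log2(TPM + 1) averaged 0.141, or 0.682 of the mean within lanes.

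Within Lane 1, HSPA8, LIN28A and POU5F1 varied little, with an SD of log2(TPM + 1) of 0.055, 0.052 and 0.077 over 95 libraries. The 10 most variable genes among those with a mean of at least 1 TPM had an SD of 1.86 to 2.80, against a median of 0.312 over 12597 genes. They were CKMT1A and CKMT1B, copies of a mitochondrial creatine kinase, SERF1A and SERF1B, CBWD5 and CBWD6, and the read-through models PMF1-BGLAP, NEDD8-MDP1, MSANTD3-TMEFF1 and ANKHD1-EIF4EBP3. CKMT1B was at 0 in 27 libraries and reached 135.1 TPM in another, and such values of genes that share reads are uncertain.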

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

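The test of a lower share of pluripotent cells was written after the lists it uses had been seen, as was that of variances within families, and splits within pairs were added after the counts of genes were known. Tests of GC content, length, depth and other splits were written before their results.

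Within the 6 libraries of Lane 4, 8 values (6.20% of those tested) had 1 library far from the rest, where chance gives about 1 in 20. They involved 5 different libraries. The gap to the nearest library, as a share of the range, was 1 for HIST1H4J, which was above 0 in only 1 library, against a critical value of 0.625. It was 0.691 for FOXA3, 0.709 for ADM and 0.646 for CYP51A1, each with 1 low library. Among list means it was 0.762 for neuroectoderm, with 1 low library, and 0.658 for neural crest, 0.657 for endoderm and 0.626 for imprinted genes, each with 1 high library.

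The pluripotency list was lower in H1p43, with a median log2 fold change of -0.52 over 22 genes. After a trend on GC content and transcript length was removed, the median was -0.4745 ± 0.128 (SE), which argues against that bias as the whole cause. The test assumed that a lower share of pluripotent cells raises markers of every other type. The median was -0.98 ± 0.61 for mesoderm and -0.52 ± 0.59 for endoderm, against 0.52 ± 0.23 for neuroectoderm and 0.39 ± 0.15 for fibroblasts. On the TPM scale the medians were -0.61 ± 0.32, -0.02 ± 0.44, 0.49 ± 0.29 and 0.39 ± 0.13. The mesoderm value rests on 7 genes (5 on the TPM scale) and is under 2 SE from 0 on both scales. A lower share could also come with a rise of only some other types, so this test cannot decide the question. The median of amnion or trophoblast was -0.65 over 5 genes and 0.66 over 3 genes on the TPM scale, where both scale and genes differ. A difference between the cells that the labels H1p16 and H1p43 mark stays open, untested.

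Cytosolic ribosomal protein genes were lower in LM-Seq Lane 4 than in TruSeq, with a median of -0.99. Genes outside the list matched on GC content had a median of 0.0729 ± 0.0477, which argues against GC content. Genes matched on length had a median of -0.51 ± 0.07, just past the bound of -0.49 set for a loss of short transcripts, by less than 1 SE. Such a loss may therefore account for about that part of the pattern, and the rest stays open. No biological explanation was tested, since the labels do not say whether the same culture of H1 was used.

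Genes that share reads led the spread in Lane 1. In 10 families, chosen after the variable genes were seen, the variance of the summed CPM was 0.157 ± 0.109 (SE) of the sum of the members' variances, as a median. Members that vary independently give 1, and a division of reads within families gives less. The ratio was under 0.5 in 8 families but 0.867 for the read-through family of NEDD8 and 0.680 for that of TMEFF1, where such a division explains less. Over the 6 shared numbers, the SD of family members in Lane 4 was 0.497 of that in Lane 1, barely under the bound of 0.5 set for shallow depth, but the ratio over all genes was 0.577, so that test separates them little. Both explanations may hold together, and no biological explanation was tested.

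For H1p43 against H1p16, 1 of 10 splits, the real one, called as many as 10460 genes, and the highest other called 0; so few splits cannot give a share under 0.05. For Lane 4 against TruSeq, 1 of 100 splits, the real one, called as many as 9852. The highest other called 4804 genes, which shows a structure of the samples, and the median of the others was 0. Other splits mix H1p16, H1p43 and LM-Seq libraries, so few calls were likely from the start. This test covers only how these libraries were assigned and cannot exclude a chance difference between cultures or preparations. For Lane 2 and Lane 3, 0 genes were called by edgeR without a block, and 0 by DESeq2 and by limma. At an unadjusted edgeR p below 0.05 there were 182 and 216, fewer than chance gives. Every split calls at least 0 (30 of 30 and 50 of 50), so those splits decide nothing. The highest other called 3 genes for Lane 2 and 1.15% of the genes tested for Lane 3, and the cause of these calls was not tested. With the replicate block, splits that part every pair were used. For Lane 2, 1 of 21, the real one, called as many as 26 genes (highest other 0). For Lane 3, 1 of 40, the real one, called as many as 44 (highest other 5). Only 21 and 40 of the possible splits were used, so each share is the smallest that this number can give. Both lie under 0.05, that of Lane 2 only just, which argues weakly against chance within pairs. For Lane 4 against Lane 1, 5 of 100 splits called at least the real 2 genes, with a highest other of 43. Chance is therefore not excluded by this test. These splits leave both libraries of some numbers on one side, which may add to the 43. Among the 32 splits that part every pair, only the real one reached 2 without a block (highest other 1) or 13 with it. With the block the other splits called up to 10 genes (median 4), so much of the 13 can arise without a lane difference.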

How the results depend on the processing

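Thinning for H1p43 against H1p16 and a variance trend in camera were chosen after seeing the data. For H1p43 against H1p16 the count of 10460 went to 1061 with a fold change of at least 2, by construction, and otherwise ranged from 9491 (DESeq2) to 10686 (no filter). Leaving out each replicate gave 9828 to 10470. Same-numbered replicates did not deviate together (correlations of 0.011 to 0.042; 2 of 3 closest to their own number), and the replicate block gave 10463. For Lane 4 against TruSeq the count of 9852 went to 3329 with a fold change of at least 2 and otherwise ranged from 8950 (Lane 1) to 10436 (no filter). No named gene reversed; 4 named genes lost their call in at least 1 setting in the former comparison and 8 in the latter.

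Between lanes, the replicate block gave 26, 44 and 13 genes for Lanes 2, 3 and 4 against 0, 0 and 2 without it, and the block on thinned counts 6, 14 and 4. In these blocked fits the common dispersion lay at the lower limit of its estimate. Lane 2 gave 1 with no filter. Lane 3 gave 60 with all libraries. Lane 4 gave 0 with thinned counts and 0 with all libraries. The cause was not tested. Lists were tested only for Lane 4 among lanes, where the block left 0 called. The 6 lists called for H1p43 against H1p16 became 0 with an estimated correlation, 23 with fry, 7 with the variance trend and 7 with the replicate block. By camera, the trend added fibroblast or stroma (adjusted p = 0.0375, and up to 0.360 in other camera settings). The block added replication-dependent histones (adjusted p = 0.0440 by camera, and up to 0.556 in other camera settings). Fry gave these lists an adjusted p of 2.8e-05 and 0.0022. The adjusted p of the 6 lists stayed at or below 0.0256 with camera's preset correlation. For Lane 4 against TruSeq 1 list became 0 with an estimated correlation and 22 with fry. Fry poses another question, whereas the estimated correlation repeats that of camera. The gain in genes detected in Lane 4 fell to 32.5 on thinned counts, and the spread ratio of 0.682 moved to 0.665 at a mean of at least 10 TPM and 0.789 on thinned counts. Depth limits Lane 1 most, where 1040667 to 1539268 counts per library left 13260 genes detected.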

Other observations

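The metallothionein and SR splicing factor lists, and the comparison of LM-Seq with each TruSeq group, were chosen after seeing the data, so no p is given for these lists. All 7 metallothioneins tested fell in H1p43, with a median log2 fold change of -5.28, or -4.10 with MT1M, at 0 in H1p43, at its bound of at least 16.9-fold lower. MT1X, the most abundant, went from 636 ± 21.3 to 192 ± 9.61 TPM (SD, n = 3). Of 12 SR splicing factors, 10 fell and 2 rose (median -0.52). SRSF6 (-1.12 ± 0.02), SRSF7 (-1.07 ± 0.02) and SRSF3 (-0.96 ± 0.02) led the decreases (SE).

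Signalling genes split between directions in H1p43. The immediate early factors FOS (-1.58 ± 0.08) and JUN (-1.19 ± 0.08) fell and NR4A1 rose (1.15 ± 0.06), in a list where 9 of 19 fell and 7 rose. Among targets of NODAL and TGF-beta, GDF3 fell (-1.42 ± 0.07) and LEFTY1 rose (0.85 ± 0.08). ASNS (0.64 ± 0.03) and DDIT4 (1.23 ± 0.06), induced by the stress factor ATF4, rose, whereas the endoplasmic reticulum chaperone HSPA5 fell (-0.53 ± 0.02). None of these 3 lists passed camera, with adjusted p of 0.655, 0.727 and 0.655.

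The next count left out Y-linked genes and a gene of X inactivation. Of 828 genes at least 2-fold higher in H1p43 than in H1p16, most had a mean log2(TPM + 1) in LM-Seq nearer to H1p16. These were 747 in Lane 4 (90.2%) and 784 in the shallower Lane 1 (94.7%). The same held for 63.2% and 58.9% of 231 lower ones. For the higher genes H1p16 is the low group, so a loss of signal in LM-Seq also counts as nearer to it. Detection averaged 14831 genes in Lane 4 and 13260 in Lane 1, against 16446 in H1p16. The 828 genes alone therefore cannot tell which TruSeq group the LM-Seq cells resembled. NPTX1 averaged 1.76 ± 0.59 TPM in Lane 4 against 1.94 TPM in H1p16 and 25.4 TPM in H1p43, and MT1G 83.1 ± 11.9 TPM against 199 and 3.39 TPM. HES3 lay nearer to H1p43, at 23.5 ± 7.60 TPM in Lane 4 against 73.5 and 15.9 TPM. The correlation over genes between Lane 4 and TruSeq libraries was 0.965 to 0.971 for H1p16 and 0.954 to 0.959 for H1p43. Protocol differs between these libraries, and which culture of H1 LM-Seq used is not given in the sources used here.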
